A study of Mus musculus with 8 samples.

How the data were processed

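The jejunum of naive, co-housed C57BL/6 (B6) and C3H/HeJ (C3H) mice was profiled by bulk RNA sequencing, with 4 libraries per strain. Per the labels, total RNA was extracted with a Qiagen miRNeasy kit and 200 ng of RNA with an integrity number above 7 went into the Illumina Stranded mRNA preparation. The authors aligned reads with STAR 2.7.9a to GRCm39 and counted them per gene with HTSeq 2.0.2. The deposited table holds raw counts for 56941 Ensembl gene identifiers in 8 libraries, and it was used without further rescaling by the authors. The annotation release and the strand setting of the counting are not given in the sources used here. Gene symbols, chromosomes and gene order came from GENCODE M21, an annotation of the earlier build GRCm38, so no coordinates are given; 51948 identifiers had a symbol there and 4993 had none. Of 638 symbols in the fixed gene lists 635 were found, some under an older symbol.

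Each sample was placed in its strain from its label, and C3H was compared with B6, the only comparison that the labels define. Counts were fitted in edgeR 4.0.16 under R 4.3.3 with TMM scaling, filterByExpr by strain at its default minimum count of 10, and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the 18025 genes tested and a threshold of 0.05. Log2 fold changes are C3H over B6, CPM values use TMM-scaled library sizes, and standard errors were back-calculated from the fold change and the F statistic. The total per library was 37205896 to 58251332 counts, the TMM factors were 0.915 to 1.13, and mitochondrial transcripts took 3.61% to 5.08% of counts. Between libraries of 1 strain the chi-square over its degrees of freedom was 23.3 to 89.6, so no pair was a technical copy at counting noise. A gene with 0 counts in a strain was given a bound at a floor of 3 counts over that strain, and a gene with 1 to 3 counts the ratio with a 95% counting interval. Separation by strain was measured by Spearman correlation and principal components of log2 CPM with a prior count of 2.

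The test, the gene lists, the rule for naming genes and all but 1 of the alternatives were chosen before the data were examined. The lists were the cysteinyl leukotriene pathway, other eicosanoids, epithelial junctions, antigen transport and M cells, type 2 immunity, class I and class II presentation, interferon-stimulated genes, inducible defence, microbe sensing, lipid absorption, brush border, xenobiotic metabolism, clock genes, immediate early and heat shock genes, proximal and distal small intestine, pancreas, adipose tissue, erythroid cells, mast, tuft, goblet, Paneth and enteroendocrine cells, stem cells, proliferation, plasma and B cells, T cells and intraepithelial lymphocytes, macrophages and dendritic cells, neutrophils, smooth muscle, fibroblasts, endothelium, and enteric neurons and glia. Each was tested with camera (limma 3.58.1) at the preset correlation of 0.01 and with an estimated one, and with fry, adjusted over the 35 lists. At the preset correlation 13 lists passed, with an estimated correlation 0 (camera), and with fry 14.

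The genes named were all tested members of the leukotriene pathway; the 10 with the largest fold change per direction among those with at least 5 CPM in the higher strain and no overlap between strains, unnamed models left out; the 5 per direction with the largest CPM difference among those changed at least 2-fold; up to 4 members per list with the smallest adjusted p, or the 2 most abundant where none passed; and genes that check the strain or sex. This rule named 163 genes. Kit, Hdc, Gzma, Gzmb, Cd4, Xcl1, Pou2f3, Tas1r3, Ciita, Lyz1, Cyp2c29 and Cyp3a13 were list members named after their values were seen.

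Alternatives were DESeq2 size factors, upper-quartile factors and library totals, no filter and a mean of at least 100 counts, DESeq2 1.42.0, limma-voom, robust dispersion, leaving out copy families and unnamed gene models, leaving out the sex chromosomes and the mitochondrial genome, a threshold of 0.01, a block for the replicate numbers that both strains share, each library left out in turn and, for the separation, the 500 most variable genes. Leaving out the 4 libraries richest in pancreatic transcripts was chosen after seeing the data. The method was tested on simulated data with the depth of these libraries. Each gene was given the spread that the trend over all genes sets for its abundance, so differences in spread between genes of like abundance were left out. At each fold 50 of 18025 genes were changed, a far smaller share than the 21.4% called in the data. The rates below may therefore not carry over to the real comparison. edgeR recovered 32% of genes changed 1.5-fold, 78% at 2-fold, 94% at 4-fold and 94% at 8-fold, with 4 false calls of 153; limma-voom made 2 false calls of 150 and DESeq2 20 of 177. Camera called the 1 raised list and 0 of 34 unchanged lists, and fry 0 of 34. The simulated genes varied independently of each other, whereas the correlation estimated within the real lists reached 0.893 (adipose tissue). The simulation therefore does not show how often camera or fry calls unchanged lists of correlated genes.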

Results

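Bulk RNA sequencing of the jejunum, the middle part of the small intestine, was compared between naive mice of 2 inbred strains, C57BL/6 (B6) and C3H/HeJ (C3H). Per the labels, mice of 6 to 8 weeks were housed together for at least 8 weeks before harvest; whether that age is the one at the start of housing is not stated. The series title links food anaphylaxis in mice to allergen absorption that depends on cysteinyl leukotrienes, lipid mediators made from arachidonic acid. The strain comparison addresses how the unchallenged intestine differs between these strains. There were 8 libraries, 4 from B6 (replicates 2, 3, 4 and 5) and 4 from C3H (replicates 1, 3, 4 and 5), and the labels place all of them in batch 1. Total counts ran from 37205896 to 58251332 per library, and 25155 to 26483 genes had at least 1 count. The labels do not say whether each library came from a separate mouse, so the p-values measure the spread between these libraries.

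Across the tested genes the strains differed widely. Of 18025 genes tested, 3857 (21.4%) changed, 2040 of them higher and 1817 lower in C3H (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With library totals only as scaling, 2194 genes were higher and 1402 lower. Changes of at least 2-fold were found for 1417 genes, 776 higher and 641 lower, while 1374 changed genes differed by at most 1.5-fold. The 4 values of 1 strain lay wholly above those of the other for 4405 tested genes (24.4%), against 2.86% by chance. The libraries grouped by strain: the mean Spearman correlation was 0.990 within strains and 0.967 between them, and none of the other splits of the 8 libraries into 4 and 4 gave as large a difference (exact permutation p = 0.0286, one-sided, the smallest that 35 splits allow). With the 4 libraries richest in pancreatic transcripts left out (B6 2, B6 3, C3H 3 and C3H 5), an alternative chosen after seeing the data, the 2 libraries left per strain gave 1675 changed genes.

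**Figure D1:**
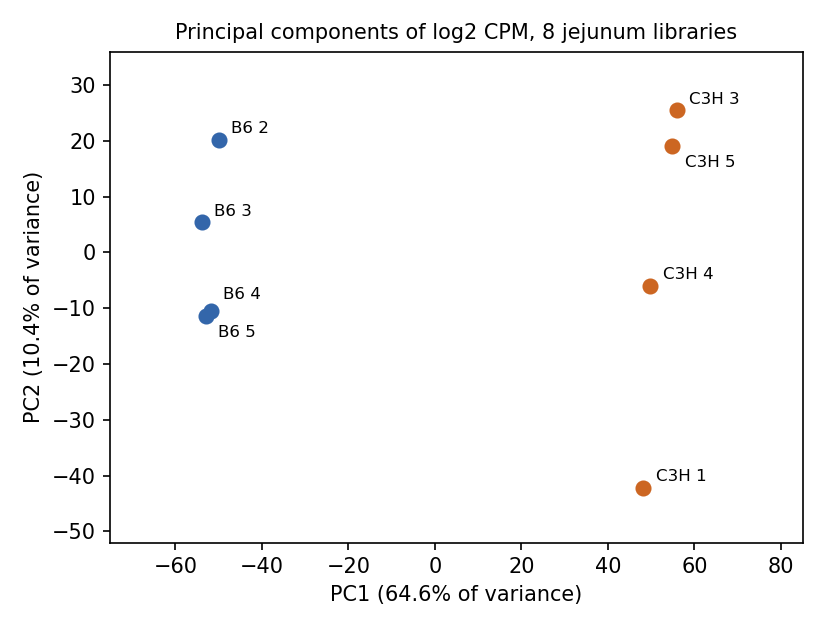
Principal components of log2 CPM (read counts scaled to library size) over the genes tested, 1 point per library, B6 in blue and C3H in orange. On the first component (64.6% of variance) all B6 libraries lie below 0 and all C3H libraries above 0, and on the second (10.4%) C3H 1 is lowest, at -42.2.

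Among genes fixed as checks of the strains, H2-Ea (ENSMUSG00000036322), a class II histocompatibility gene that B6 mice do not transcribe and that the annotation names H2-Ea-ps, had 4 counts over the B6 libraries and 17663 over the C3H libraries. Its log2 fold change was 12.02 (standard error 0.37, adjusted p = 3.09e-09), and 15.12 without B6 5, which held all 4 B6 counts. Pla2g2a (ENSMUSG00000058908), a secreted phospholipase of Paneth cells that is inactive in B6, was 127-fold higher in C3H (678 ± 220.0 against 5.34 ± 1.41 CPM, SD, n = 4 each). Glo1, which detoxifies methylglyoxal, rose 2.48-fold. Tpsab1, a mast cell tryptase, had 67 counts in C3H and 3 in B6, a ratio of 23.2 (95% counting interval 7.61 to 115); its fitted log2 fold change moved from 4.30 to 5.28 without B6 3. Tlr4, the lipopolysaccharide receptor whose protein carries a loss-of-function change in C3H/HeJ, did not pass the threshold (log2 fold change 0.08, standard error 0.22, adjusted p = 0.837), nor did Itln1 (0.11, adjusted p = 0.722) or Ly6a (0.15, adjusted p = 0.242). Nnt had 6 to 17 counts per library and was not tested. Xist had 9969 to 19433 counts per library (adjusted p = 0.437 between strains), and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all 8.

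The largest fold changes came from genes nearly absent in 1 strain. Retnlb, a secreted goblet cell protein of the resistin family, was 211-fold higher in C3H (56.0 ± 11.1 against 0.283 ± 0.325 CPM, SD, n = 4 each), Nat8f7 65.7-fold and the defensin Defa35 119-fold. Ifi44l had 0 counts in B6 and 894 in C3H, at least 309.7-fold higher at a floor of 3 counts over the strain, and the kallikrein Klk1b22 had 1 and 998 counts, a ratio of 1037 (interval 186 to 41002). Among immunoglobulin heavy chain segments, Ighv1-62, Ighv1-23 and Ighv1-37 rose (log2 fold changes 6.10, 7.01 and 6.87) and Ighv1-14 had 2 and 6401 counts, a ratio of 3326 (920.3 to 27468). In the other direction, Trim12a had 11049 counts in B6 and 1 in C3H (ratio 10633, interval 1908 to 420012). The Paneth cell defensins Defa21 and Defa22 had 0 counts in C3H and were at least 1228-fold and 929-fold lower, as were the segments Ighv1-54, Ighv4-1, Ighv1-9 and Ighv1-76, at least 305-fold, 413-fold, 1094-fold and 517-fold lower. Ighv9-3 and Ighv9-1 had 1 and 2 counts in C3H (ratios 6718 and 651, intervals 1205 to 265387 and 179.9 to 5381), and Ighv2-3 was 163-fold lower.

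Single libraries moved several of these near-absent genes. The fitted log2 fold change was 8.66 for Retnlb, 8.53 for Ighv1-37 and -7.09 for Ighv9-1 without B6 2, -10.96 for Ighv1-76 without B6 3, and 10.95, 13.61, 7.58, 8.70 and -11.86 for Klk1b22, Ighv1-14, Ighv1-62, Ighv1-23 and Ighv1-9 without B6 5. It was -14.39 for Trim12a without C3H 1, and -13.71 and -11.56 for Ighv9-3 and Ighv9-1 without C3H 3, against 7.72, 6.87, -9.24, -11.65, 9.42, 11.35, 6.10, 7.01, -12.61, -12.81 and -12.13 with all libraries, in the order of first naming. Defensin and immunoglobulin genes have close copies that can share reads, so their values are uncertain, and intervals and floors cover counting error only. In this ranking 8 unnamed gene models with larger rises and 2 with larger falls were passed over.

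Measured by CPM, the sialyltransferase gene St3gal4 (ENSMUSG00000032038) was 131-fold lower in C3H (1629 ± 41.8 to 12.4 ± 2.01 CPM, SD, n = 4 each, adjusted p = 2.90e-10). The mucin gene Muc3 fell 4.59-fold from 4751 ± 2045 CPM, Cd74, the class II invariant chain, 3.53-fold and the class I gene H2-K1 2.27-fold. Reg3b, an antimicrobial lectin, fell 3.77-fold (adjusted p = 0.0379). It belongs to a family of similar genes, so its value is uncertain. The call of Reg3b ended without any 1 of B6 2, B6 3, B6 5, C3H 1, C3H 3 or C3H 5 (adjusted p up to 0.0979), and its log2 fold change moved from -1.91 to -2.75 without C3H 4. Besides Pla2g2a, the genes that rose most in CPM among those changed at least 2-fold were Adh1, the retinol-oxidising alcohol dehydrogenase (701 ± 103 to 2104 ± 413 CPM), Aldh1a1, a retinaldehyde dehydrogenase (2.17-fold), the carboxylesterase Ces2a (2.51-fold) and Akr1c19 (2.64-fold).

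Genes of the cysteinyl leukotriene pathway moved in both directions. Of 15 tested members, 4 rose and 4 fell, with the same counts adjusted over the list alone. Gpr17 (ENSMUSG00000052229), a receptor reported to respond to leukotrienes, rose 3.15-fold (9.06 ± 1.13 to 28.6 ± 7.25 CPM, SD, n = 4 each; log2 fold change 1.66, standard error 0.17, adjusted p = 3.68e-05). Mgst2 and Mgst3, microsomal glutathione transferases that can act on leukotriene precursors, rose 1.76-fold and 1.31-fold, and Ggt5, which trims the glutathione part of the first cysteinyl leukotriene, rose 1.40-fold. The 5-lipoxygenase gene Alox5 (log2 fold change -0.47, standard error 0.14) and its partner Alox5ap (-0.54, 0.16) fell, as did the receptor gene Cysltr2 (-0.83, 0.19, adjusted p = 0.0102) and P2ry12 (-1.31, 0.29, adjusted p = 0.00753). Alox5ap is also on the list of tuft cell genes, so its fall was not separated from tuft cell content.

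The pathway genes with the highest counts among the rest did not pass the threshold. Ggt1 averaged 1249.5 CPM in B6 and 1022 in C3H (log2 fold change -0.29, standard error 0.18), and Dpep1, a dipeptidase that acts on cysteinyl leukotrienes, 426 and 484 CPM (0.18, 0.13). The log2 fold change was -0.24 for Ltc4s, which makes the first cysteinyl leukotriene, -0.15 for the exporter Abcc1, -0.07 for Ggt6, -0.10 for the receptor Cysltr1 and 0.01 for the phospholipase Pla2g4a. Dpep2, Dpep3 and Oxgr1 were not tested, with 10, 6 and 0 counts in B6 and 14, 8 and 1 in C3H. As a set the list showed no direction: the median was -0.10 and the mean -0.03, camera pointed down (adjusted p = 0.707) and fry up (adjusted p = 0.987). Fry's test for change in either direction gave an adjusted p of 7.58e-06. That test asks whether members changed and does not compare them with genes outside the list. All other lists passed it too, except pancreas, adipose tissue, proliferation, smooth muscle, fibroblasts, and enteric neurons and glia. It therefore does not set the leukotriene genes apart.

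Several of the smaller leukotriene calls were lost in fits with 1 library left out. Without B6 3, 5 members passed, 2 of them higher, and without B6 5 or C3H 4, 2 members fell. Ggt5 was lost without B6 3 or C3H 3 (adjusted p up to 0.0632), Mgst3 without B6 2, B6 3 or B6 4 (up to 0.0669), Alox5 without B6 3, B6 5, C3H 3, C3H 4 or C3H 5 (up to 0.0844) and Alox5ap without B6 4, B6 5, C3H 1 or C3H 4 (up to 0.0920), each with 1 library left out at a time. Ggt1 passed the threshold without C3H 5 (log2 fold change -0.48, adjusted p = 0.0279). Without the 4 pancreas-rich libraries 2 members passed.

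**Figure D2:**
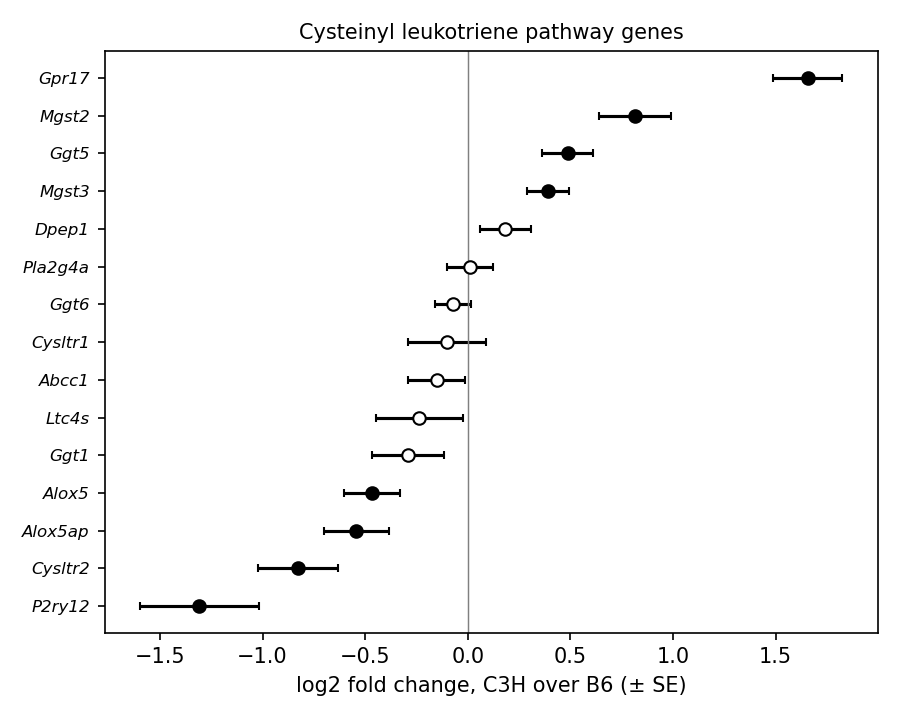
Log2 fold change, C3H over B6, of the 15 tested genes of the cysteinyl leukotriene pathway, with bars of 1 standard error; filled points have an adjusted p under 0.05 and open points do not. Gpr17 (1.66) and P2ry12 (-1.31) are the ends of the range, with 4 filled points on each side of 0.

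Other eicosanoid genes that changed were all higher in C3H. Besides Pla2g2a, the lipoxygenase genes Alox15 and Alox12 rose 2.07-fold and 1.76-fold, and the prostaglandin D2 receptor gene Ptgdr2 rose 3.10-fold on 27 and 82 counts. In all 6 of 23 rose (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0475, and adjusted p = 0.341 with an estimated correlation), and 1 fell without B6 2 or C3H 5. Type 2 immunity genes moved both ways: Il33, the epithelial and stromal alarmin, fell 2.04-fold (90.8 ± 11.3 to 44.4 ± 2.27 CPM, SD, n = 4 each; adjusted p = 2.41e-05), the eosinophil granule gene Prg2 2.60-fold and the interleukin-9 receptor gene Il9r 2.15-fold, while the eosinophil attractant gene Ccl11 rose 2.19-fold. In this list 2 of 16 rose and 4 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.0973, fry 0.00730). Counts were too low to pass the filter of the main fit for Il4 (11 in B6, 19 in C3H), Il5 (2, 0), Il13 (3, 1) and Il25 (20, 7).

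Mast cell genes were higher in C3H. Cpa3 (ENSMUSG00000001865), the mast cell carboxypeptidase, rose 9.41-fold (0.225 ± 0.0424 to 2.10 ± 0.396 CPM, SD, n = 4 each; adjusted p = 2.09e-06), the mucosal protease gene Mcpt2 by 3.33 on the log2 scale, Mcpt4 13.2-fold and the tryptase gene Tpsb2 5.79-fold. Kit, the stem cell factor receptor, which other intestinal cells also express, rose 1.45-fold, and Hdc, the histamine-making enzyme, fell by 0.78 on the log2 scale. Of 12 tested markers 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a median log2 fold change of 2.82 (camera adjusted p = 0.000142, and adjusted p = 0.204 with an estimated correlation). Hdc was lost without any 1 of B6 3, B6 4, B6 5, C3H 1, C3H 3, C3H 4 or C3H 5 (adjusted p up to 0.0938). Levels in B6 were low, with 41 counts for Cpa3 and 22 for Mcpt4, and 3 markers passed where a mean of at least 100 counts was required. Pancreatic transcripts were also highest in C3H libraries (2910.2 and 1307 CPM in C3H 3 and C3H 5, against 45.2 to 270.1 in B6).

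**Figure D3:**
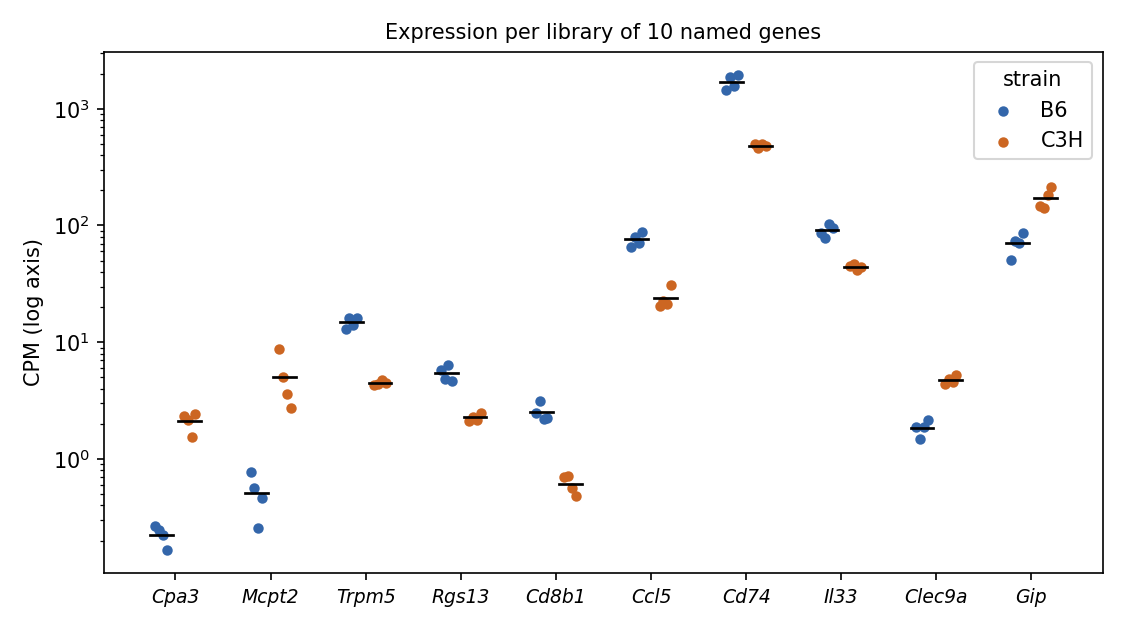
CPM per library, on a log axis, of 10 named genes; each point is 1 library, B6 in blue and C3H in orange, and the black lines are means of 4. Mast cell, dendritic cell and hormone genes (Cpa3, Mcpt2, Clec9a, Gip) lie higher in C3H and tuft cell, T cell and class II genes (Trpm5, Rgs13, Cd8b1, Ccl5, Cd74) and Il33 lower, without overlap between strains.

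T cell and intraepithelial lymphocyte genes were lower in C3H. The chemokine gene Ccl5 (ENSMUSG00000035042) fell 3.20-fold (76.3 ± 10.1 to 23.9 ± 4.76 CPM, SD, n = 4 each), Cd8b1, a chain of the CD8 co-receptor, 4.01-fold, the killer cell receptor gene Klrd1 3.90-fold and the T cell receptor constant gene Trac 2.65-fold. Klrd1 and Trac belong to families of similar genes, so their values are uncertain. The cytotoxic granule genes Gzma and Gzmb fell 2.50-fold and 2.19-fold, while Cd4, the helper T cell co-receptor gene, and the chemokine gene Xcl1 rose 1.34-fold and 2.22-fold. Of 21 tested markers 18 fell and 2 rose, with the same counts adjusted over the list alone and a median log2 fold change of -1.10 (camera adjusted p = 8.14e-11, and adjusted p = 0.204 with an estimated correlation).

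Genes of tuft cells, chemosensory cells of the epithelium, were lower in C3H. The taste channel gene Trpm5 (ENSMUSG00000009246) fell 3.32-fold (14.8 ± 1.59 to 4.46 ± 0.171 CPM, SD, n = 4 each), Rgs13 2.39-fold, Sh2d7 2.35-fold and Lrmp, also called Irag2, 1.74-fold. The lineage factor gene Pou2f3 fell 2.51-fold and the taste receptor gene Tas1r3 rose 2.11-fold. Of 16 tested genes 12 fell and 1 rose, with the same counts adjusted over the list alone (median -0.89, camera adjusted p = 1.61e-06, and adjusted p = 0.204 with an estimated correlation).

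Antigen presentation genes that changed were mostly lower in C3H. Of the class II genes, H2-Ab1 (ENSMUSG00000073421) fell 8.65-fold (979 ± 119.9 to 113 ± 4.60 CPM, SD, n = 4 each), H2-DMb1 11.5-fold and H2-Aa 3.99-fold. Outside the H2 complex, Cd74 fell by 1.82 on the log2 scale (standard error 0.12, adjusted p = 1.50e-06) and the class II transactivator gene Ciita fell by 0.84. Of the class I genes, H2-Q2 fell 41.9-fold (1236 ± 108 to 29.5 ± 3.62 CPM), H2-Q6 21.5-fold and H2-D1 3.48-fold, and H2-Q7 fell by 5.65 on the log2 scale. In class II 7 of 12 fell and 2 rose, the same adjusted over the list alone, with a median of -1.30 and, through H2-Ea, a mean of -0.17 (camera adjusted p = 0.000281, and adjusted p = 0.616 with an estimated correlation). In class I 12 of 21 fell and 4 rose, the same over the list alone (median -0.43, camera adjusted p = 0.000281, and adjusted p = 0.779 with an estimated correlation). The strains carry different haplotypes of the H2 complex, whose genes are close copies counted here against a B6-derived genome, so the H2 values are uncertain. With copy families left out, 2 class II and 5 class I members were left as changed, and 9 class I members passed without the 4 pancreas-rich libraries.

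**Figure D4:**
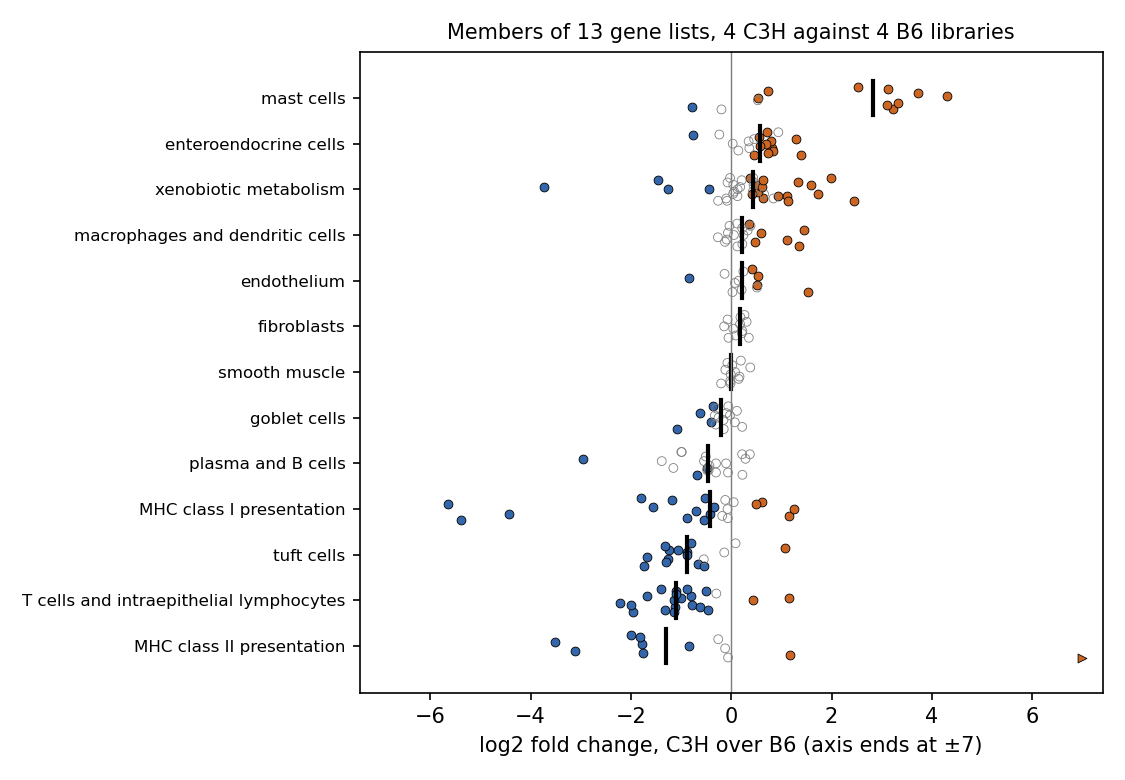
Log2 fold change, C3H over B6, of each tested member of 13 gene lists; filled points have an adjusted p under 0.05 (orange higher, blue lower in C3H), open points do not, black lines are list medians, and an arrowhead marks a member beyond the axis end of 7. Mast cell genes lie mostly to the right (median 2.82) and tuft cell, T cell and class II genes mostly to the left (medians -0.89, -1.10 and -1.30).

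Sensing and defence genes moved in both directions. Of those named below, Nlrp1b, Gbp6, Gbp2 and Reg3a belong to families of similar genes, so their values are uncertain. Among microbe sensors, the inflammasome gene Nlrp1b fell 18.1-fold and Ly96, the partner of the lipopolysaccharide receptor, 3.53-fold, while the co-receptor gene Cd14 and the DNA sensor gene Aim2 rose 4.51-fold and 2.88-fold; 3 of 30 rose and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.169, fry 0.00104). Among interferon-stimulated genes Gbp6 fell 9.26-fold, Gbp2 1.85-fold and the chemokine gene Cxcl10 1.88-fold, and the nucleic acid sensor gene Zbp1 fell from 88.7 to 44.5 CPM. In that list 1 of 30 rose and 6 fell, the same over the list alone (camera adjusted p = 0.169), and 4 members passed without B6 2; 0 rose in edgeR without B6 2 or B6 5 and 2 without B6 3. The median of -0.06 was 0.06 without B6 3, 0.01 without C3H 1, 0.02 and 0.04 in the 6 libraries with shared replicate numbers (without and with a block), and 0.18 without the 4 pancreas-rich libraries, where 4 rose and 2 fell. Among inducible defence genes Reg3a rose 1.78-fold and the oxidase genes Duox2 and Duoxa2 fell 5.73-fold and 7.14-fold; 2 of 18 rose, Retnlb among them, and 5 fell (2 and 6 over the list alone). With 1 library left out, 3 fell without B6 2, B6 3, B6 5, C3H 1, C3H 3 or C3H 5, 6 without B6 4 and 7 without C3H 4. Their median was -0.23 (0.08 without copy families) and camera pointed down (adjusted p = 0.456), whereas fry pointed up (adjusted p = 0.987).

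Paneth cell genes that moved were mostly defensins. Defa26 and Defa3 fell 14.6-fold and 15.6-fold, and Defa34 had 870 counts in B6 and 3 in C3H (ratio 279, interval 95.2 to 1356; fitted log2 fold change -7.96, and -10.76 without C3H 1). Lyz1, the Paneth cell lysozyme gene, averaged 1579 and 1388 CPM (log2 fold change -0.19, adjusted p = 0.475). Of 21 genes 2 rose and 9 fell (3 and 9 over the list alone; median -0.19, mean -2.08, camera adjusted p = 0.00757, and adjusted p = 0.779 with an estimated correlation). With copy families left out, 1 member was left as changed and the median was 0.30.

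Digestive genes that changed were lower in C3H. The subunit genes of the protease meprin, Mep1a (ENSMUSG00000023914) and Mep1b, fell 14.4-fold (185 ± 36.3 to 12.8 ± 1.24 CPM, SD, n = 4 each) and 1.58-fold, the peptidase gene Naaladl1 2.07-fold and Dpp4 1.39-fold. In all 5 of 27 brush border genes fell, the same over the list alone (median -0.20, camera adjusted p = 0.00186, fry adjusted p = 0.0577, and camera adjusted p = 0.779 with an estimated correlation). Without C3H 3, 3 members passed, and Dpp4 did not (adjusted p = 0.0735); without C3H 1, 1 member rose. Among lipid absorption genes the lipid droplet gene Plin2 rose 1.59-fold, and the cholesterol transport and storage genes Abca1, Soat2 and Npc1l1 fell 2.24-fold, 1.41-fold and 1.42-fold. In that list 2 of 23 rose and 3 fell, the same over the list alone (camera down, adjusted p = 0.740; median -0.01, mean 0.01). The median was above 0 with library totals only, with a mean of at least 100 counts, in the 6 libraries with shared replicate numbers, and without B6 4 or C3H 1. Npc1l1 was lost without C3H 3 (adjusted p = 0.0559), and 8 members passed without C3H 1. The number higher was 1 without B6 2, 4 without B6 4 and 5 without C3H 1.

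Xenobiotic metabolism genes were more often higher than lower in C3H. Besides Adh1, the carboxylesterase genes Ces1d and Ces1g rose 5.45-fold and 3.94-fold and the glucuronosyltransferase gene Ugt2b5 3.31-fold, while the cytochrome genes Cyp2c29 and Cyp3a13 fell 13.3-fold and 2.41-fold. Of 37 genes 15 rose and 4 fell (16 and 4 over the list alone; median 0.43, camera adjusted p = 0.0153, fry adjusted p = 0.128, and camera adjusted p = 0.872 with an estimated correlation). Many have close copies: 4 were left as changed without copy families, and 9 passed without the 4 pancreas-rich libraries.

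Enteroendocrine genes that changed were mostly higher in C3H. Gip (ENSMUSG00000014351), an incretin hormone gene, rose 2.44-fold (70.3 ± 14.4 to 172 ± 32.9 CPM, SD, n = 4 each), Scg5 2.63-fold, Cck 1.75-fold and Chgb 1.63-fold. Of 19 genes 11 rose and 1 fell (14 and 1 over the list alone; median 0.57, camera adjusted p = 0.000222, and adjusted p = 0.369 with an estimated correlation), and 4 passed without the 4 pancreas-rich libraries; 2 fell without B6 2. Gip and Cck are also on the list of proximal intestine genes, of which 5 of 11 rose, so position along the intestine was not separated from enteroendocrine content. Goblet cell genes that changed were lower: Fut2 fell 2.13-fold, Zg16 1.53-fold, Agr2 1.32-fold and Creb3l1 1.28-fold, 4 of 16 members, the same over the list alone (median -0.20, camera adjusted p = 0.0346, fry adjusted p = 0.0672, and camera adjusted p = 0.779 with an estimated correlation). These calls were unsteady: 2 members passed without B6 3, C3H 4 or C3H 5 and 1 without B6 5 or C3H 3. Zg16 was lost without B6 5 or C3H 3 (adjusted p up to 0.108), Agr2 without B6 2, B6 3, B6 5, C3H 3, C3H 4 or C3H 5 (up to 0.0761) and Creb3l1 without B6 3, B6 5, C3H 3, C3H 4 or C3H 5 (up to 0.103).

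Crypt stem cell genes that changed were lower in C3H. Slc14a1 fell 2.13-fold, Tnfrsf19 1.88-fold and Axin2, a Wnt target, 1.31-fold, and Axin2 was lost without any 1 of B6 2, B6 3, B6 5, C3H 3, C3H 4 or C3H 5 (adjusted p up to 0.120). In all 3 of 14 fell, the same over the list alone (camera adjusted p = 0.169), and 1 rose without C3H 5. Of 20 proliferation genes 0 passed the edgeR threshold, over all genes or over the list alone (1 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by limma-voom; camera adjusted p = 0.751). Mki67 averaged 88.5 and 92.2 CPM (adjusted p = 0.878) and Pcna 76.0 and 63.5 CPM (adjusted p = 0.0530, and 0.0220 without C3H 1).

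Genes of the epithelial barrier changed in small numbers. Among junction genes Cldn1 rose 2.52-fold from 0.352 CPM, and Cldn23, Cldn7 and Tjp3 fell 1.42-fold, 1.38-fold and 1.23-fold, so that 1 of 23 rose and 3 fell, the same over the list alone (camera adjusted p = 0.451). Without B6 3, 2 members passed; Cldn7 was lost without B6 3 or C3H 3 (adjusted p up to 0.0704) and Tjp3 without B6 3, B6 5 or C3H 5 (up to 0.0853). Among antigen transport and M cell genes Tnfrsf11a rose 1.37-fold, and Ccl9 and Spib fell 1.37-fold and 1.68-fold. In that list 1 of 12 rose and 2 fell (2 and 2 over the list alone; median -0.11, mean 0.09, camera down, adjusted p = 0.552). In edgeR fits 0 members passed without C3H 3, where Tnfrsf11a was lost (adjusted p = 0.0552), and 1 without B6 3, B6 5 or C3H 5; 2 rose without C3H 1 or C3H 4. Ccl9 and Spib were lost without any 1 of B6 3, B6 5, C3H 3, C3H 4 or C3H 5 (adjusted p up to 0.0957 and 0.102).

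Genes that mark position along the intestine also differed. Of the proximal genes, the iron reductase gene Cybrd1 and the iron exporter gene Slc40a1 rose 4.65-fold and 3.42-fold, with Cybrd1 at 53.2 CPM in C3H 5 against 14.2 to 20.7 in the other C3H libraries (log2 fold change 2.22, and 1.60 without C3H 5). With Gip and Cck, 5 of 11 rose (5 higher and 1 lower over the list alone; median 0.73, camera adjusted p = 0.0475, and adjusted p = 0.779 with an estimated correlation), and 1 fell without C3H 5. Of the distal genes, the bile acid exporter genes Slc51b and Slc51a fell 2.11-fold and 1.40-fold and the neurotensin gene Nts 1.71-fold, while the glucagon gene Gcg rose 1.61-fold. In all 1 of 9 rose and 3 fell (3 and 3 over the list alone; median -0.18, mean 0.21, camera down, adjusted p = 0.456). Without B6 3, C3H 1 or C3H 4, 2 distal genes rose. The distal median was above 0 with DESeq2 and with no filter, and Slc51a was lost without B6 3, B6 5 or C3H 3 (adjusted p up to 0.0789). Whether position along the intestine contributes to the differences in the other lists was not tested.

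Phagocyte and endothelial genes that changed were mostly higher in C3H. Clec9a and Xcr1, which mark cross-presenting dendritic cells, rose 2.55-fold and 2.18-fold, the monocyte gene Ly6c2 2.72-fold and the macrophage receptor gene Csf1r 1.27-fold. Ly6c2 belongs to a family of similar genes, so its value is uncertain. Of 19 macrophage and dendritic cell genes 6 rose (8 over the list alone; median 0.22, camera adjusted p = 0.0186, and adjusted p = 0.514 with an estimated correlation). The endothelial receptor genes Tek, Kdr, Tie1 and Flt1 rose 2.90-fold, 1.44-fold, 1.43-fold and 1.33-fold; 4 of 12 endothelial genes rose and 1 fell (5 and 1 over the list alone; camera adjusted p = 0.0878, fry 0.0354). Without C3H 1, 3 endothelial genes passed; the 1 lower call was absent in edgeR without B6 2, B6 4, C3H 1, C3H 4 or C3H 5, and Flt1 was lost without B6 3, B6 5, C3H 1 or C3H 3 (adjusted p up to 0.0644). Of 5 tested neutrophil genes Retnlg and Cxcr2 rose 1.82-fold and 2.90-fold and Mmp9 and Ltf fell 1.51-fold and 2.03-fold, the same over the list alone (camera adjusted p = 0.695, fry 0.0402). Without B6 3, 2 passed; Mmp9 was lost without B6 3 or B6 5 (adjusted p up to 0.0702) and Ltf without any 1 of B6 2, B6 3, C3H 1, C3H 3 or C3H 4 (up to 0.131). Without the 4 pancreas-rich libraries 0 neutrophil genes passed in edgeR, a fit of 2 libraries per strain.

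Plasma and B cell genes that changed were lower in C3H. The immunoglobulin constant gene Ighg2c fell 7.79-fold, the plasma cell receptor gene Tnfrsf17 1.61-fold and Jchain, the joining chain gene, 1.39-fold. These were 3 of 20 members, the same over the list alone (median -0.46, camera adjusted p = 0.306). Ighg2c belongs to a family of close copies counted here against a B6-derived genome, so its value is uncertain and its fall need not reflect plasma cell content. Without B6 3, 6 rose and 3 fell (median 0.11), and Ighg2c moved from -2.96 to -1.86 on the log2 scale. Without the 4 pancreas-rich libraries, B6 3 among them, 5 rose and 1 fell (median 0.21). Without B6 4 or without C3H 1, 5 members fell, and Jchain was lost without B6 2, C3H 3 or C3H 5 (adjusted p up to 0.0913).

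Muscle and fibroblast genes were at similar levels in both strains. Myh11 averaged 209.7 CPM in B6 and 232 in C3H, Mylk 417 and 396, Col3a1 169 and 191 and C3 105 and 101. Of 12 smooth muscle genes 0 passed the edgeR threshold, also over the list alone (0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom; camera adjusted p = 0.885), and 1 passed without B6 2. Of 12 fibroblast genes 0 passed in edgeR, also over the list alone (2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom; camera adjusted p = 0.415), with 1 past it without B6 5 and 3 without C3H 5. Among enteric neuron and glia genes the neuropeptide gene Gal rose 1.85-fold and Uchl1 fell 1.39-fold, 1 higher and 1 lower of 16, the same over the list alone (camera adjusted p = 0.664).

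Clock genes and genes that respond to handling moved in part. Per3 and Hlf rose 1.77-fold and 2.10-fold, and Arntl, the gene of the clock activator BMAL1, fell 1.96-fold; 3 of 18 clock genes rose and 2 fell (7 and 2 over the list alone; camera adjusted p = 0.169). Without B6 4, 8 rose and 2 fell, and without C3H 1, 7 rose and 1 fell. Without B6 3, B6 5 or C3H 4, 1 clock gene fell. Of the immediate early and heat shock genes Ier3 and Ier2 rose 1.45-fold and 1.21-fold and Hspa8 and Dnajb1 fell 1.40-fold and 1.19-fold, 2 higher and 2 lower of 18, the same over the list alone (median -0.07, mean 0.01, camera down, adjusted p = 0.568). Without B6 3 the median was 0.05. These calls were unsteady: 1 passed without B6 2, B6 3 or C3H 3 and 2 without B6 4 or B6 5. Ier3 was lost without B6 2 (adjusted p = 0.0521), Hspa8 without B6 3, B6 5, C3H 3 or C3H 4 (up to 0.0707), Dnajb1 without any 1 of B6 2, B6 3, B6 4, B6 5, C3H 1, C3H 3 or C3H 4 (up to 0.0983) and Ier2 without any 1 of B6 2, B6 3, B6 4, C3H 1, C3H 3, C3H 4 or C3H 5 (up to 0.138).

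Haemoglobin genes differed in both directions. Hba-a1 and Hbb-bs rose 3.29-fold and 1.63-fold and Hba-a2 fell 62.5-fold; Hba-a1 and Hba-a2 are near-identical copies, so their values are uncertain. Of 6 erythroid genes 2 rose and 1 fell, the same over the list alone (median 0.38, mean -0.48; camera up, adjusted p = 0.706, and fry down, adjusted p = 0.514). Hbb-bs was lost without C3H 3 (adjusted p = 0.0524).

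Pancreatic and fat transcripts varied between libraries of the same strain. The pancreas list summed to 2910.2 CPM in C3H 3, 1307 in C3H 5, 270.1 in B6 2, 111 in B6 3 and 45.2 to 85.5 in the other 4 libraries. Its median log2 fold change was 3.78, but 1 of 10 genes, the colipase gene Clps, passed (3.15-fold higher, the same over the list alone; camera adjusted p = 0.240). Clps was lost without B6 2, B6 3, B6 4 or C3H 3 (adjusted p up to 0.0674), and its log2 fold change of 1.66 was 0.97 without C3H 3. The fat list summed to 616 CPM in C3H 3 and 26.1 to 83.7 elsewhere; Car3 averaged 16.6 CPM in B6 and 60.9 in C3H, and Fabp4 19.2 and 32.8. Of 10 fat genes 0 passed the edgeR threshold, also over the list alone (1 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom), and the median of 1.13 stood against a camera test pointing down (adjusted p = 0.647). The fat median was -1.63 by limma-voom and -1.74 without the 4 pancreas-rich libraries. Without C3H 3 it was -1.52, with 2 of 9 genes lower, and Fabp4 had a log2 fold change of -0.60 (adjusted p = 0.0416).

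**Figure D5:**
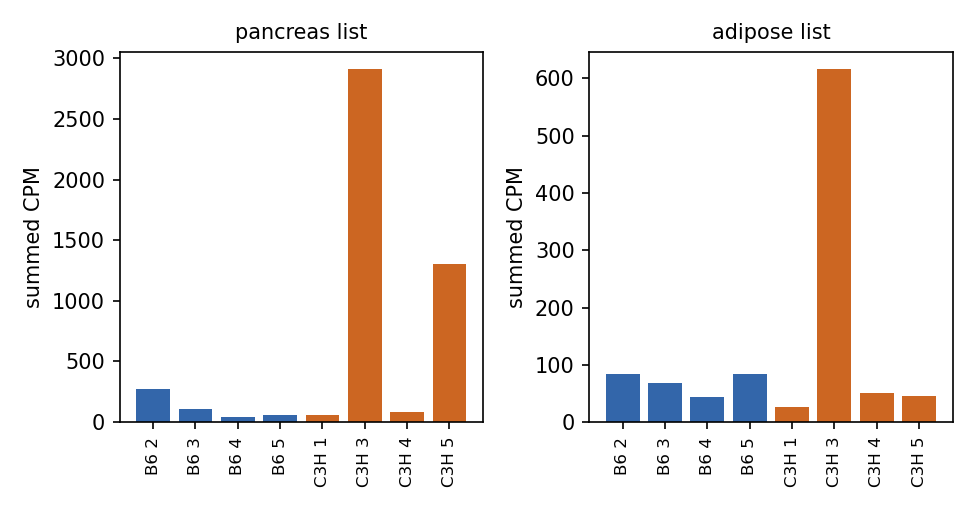
Summed CPM per library of the pancreas list and the adipose list, 1 bar per library, B6 in blue and C3H in orange. Pancreatic transcripts peak in C3H 3 (2910.2 CPM) and C3H 5 (1307), and fat transcripts in C3H 3 (616).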

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

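The values below were singled out because 1 library stood apart from the other 3 of its strain: its gap to the nearest of them, divided by the whole range of the 4 values, exceeded Dixon's critical value. This gap ratio follows each gene, and it singled out 28 of 334 groups (8.38%), where chance alone gives about 5%. No test of their origin was chosen after the result was seen, and no biological explanation was tested.

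Fat genes stood apart in 1 library and an immunoglobulin gene in another. In C3H 3 the adipose list summed to 616 CPM against 26.1 to 51.2 in the other C3H libraries (gap ratio 0.957), Fabp4 stood at 92.6 CPM against 12.5 to 13.2 (0.991) and Car3 at 226 against 0 to 9.23 (0.959). In B6 3 Ighg2c stood at 8.97 against 1.26 to 1.85 (0.924).

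Epithelial and metabolic genes stood out in single libraries. Cybrd1 was 53.2 CPM in C3H 5 (others 14.2 to 20.7, gap ratio 0.833), Aldh1a1 1478 in C3H 5 (1091 to 1109, 0.952), the tuft cell gene Lrmp 11.3 in C3H 5 (9.13 to 9.44, 0.859) and Nts 6.47 in C3H 4 (4.07 to 4.30, 0.905). Per3 was 34.99 CPM in B6 4 (23.2 to 25.1, 0.843), Slc14a1 6.22 in B6 3 (5.41 to 5.47, 0.919), Scg5 1.65 in B6 2 (2.43 to 2.49, 0.925), Jchain 1370 in B6 2 (1124 to 1154, 0.876) and Uchl1 4.45 in C3H 3 (4.04 to 4.07, 0.943). Among leukotriene genes, Mgst3 was 319 CPM in B6 5 (272 to 276, 0.923) and Ltc4s 7.01 in C3H 3 (6.14 to 6.27, 0.858).

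Genes of copy families and genes near 0 made up the rest. Ighv1-9 was 36.9 CPM in B6 5 (others 8.77 to 13.1, gap ratio 0.845), Ighv9-1 28.4 in B6 2 (0.296 to 4.37, 0.855), Ighv1-37 11.5 in C3H 1 (3.73 to 4.99, 0.839) and 0.186 in B6 2 (0 to 0.0245, 0.868), Ighv1-62 0.353 in B6 5 (0.0245 to 0.0797, 0.832) and H2-Q7 0.256 in C3H 4 (0.0806 to 0.0981, 0.9). A gap ratio of 1 means that the other 3 libraries were at 0: H2-Ea in B6 5 (0.0743 CPM), Klk1b22 and Ighv1-14 in B6 5 (0.0186 and 0.0372), Trim12a and Defa34 in C3H 1 (0.0196 and 0.0589), and Ighv9-3 and Ighv9-1 in C3H 3 (0.0192 and 0.0384). These rest on 1 to 4 counts.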

How the results depend on the processing

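The fit without the 4 pancreas-rich libraries was chosen only after the data were seen; the other alternatives were planned. The number of changed genes, 3857, was 3844 with DESeq2 size factors (3754 shared), 3946 with upper-quartile factors (3778 shared), 3596 with library totals only (3270 shared), 4278 with no filter (3523 shared), 4489 with DESeq2 (3703 shared), 3879 with limma-voom (3765 shared), 3908 with robust dispersion (3774 shared) and 3793 without the sex chromosomes and the mitochondrial genome (3770 shared). With library totals only the median of all genes was 0.09, against 0.03, and 2 neutrophil genes passed, for which the cause was not tested. Scaling cannot move the rank-based separation by strain, which was 0.0156 to 0.0309 under the 2 filters, 0.0131 without copy families and unnamed models, and 0.745 with the 500 most variable genes.

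Stricter requirements lowered counts by construction. With a mean of at least 100 counts, 1327 genes were higher in C3H, 617 changed at least 2-fold, and 3 mast cell and 1 neutrophil genes passed, since fewer genes were tested. At an adjusted p under 0.01, 2326 genes changed, 1217 higher and 1109 lower, with 3 leukotriene and 2 neutrophil genes and 8 lists. Without copy families and unnamed models, 757 genes changed at least 2-fold, and 2 class II, 5 class I, 4 xenobiotic, 0 erythroid and 1 Paneth cell genes were left in edgeR, since those families hold most of these members. With an estimated correlation camera called 0 lists, and fry 14.

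Fewer libraries lowered the number of changed genes, but not in each fit the genes changed at least 2-fold or the lists past camera. In the 6 libraries with shared replicate numbers, 3212 genes changed without and 2919 with a block for the number, 1446 and 1442 of them at least 2-fold. The block gave 5 leukotriene and 2 neutrophil genes; without it 7 leukotriene and 2 neutrophil genes passed, and the separation was 0.0247 (exact permutation p = 0.1, the smallest that 10 splits allow). Correlations of deviations for the shared numbers 3, 4 and 5 were 0.00576, 0.180 and -0.0517, within the range of -0.245 to 0.370 for pairs of unlike number. These values showed no pairing by replicate number, but so few cannot exclude it. Without the 4 pancreas-rich libraries 1675 genes changed, 853 higher and 822 lower, with 2 leukotriene, 9 class I, 9 xenobiotic, 4 enteroendocrine and 0 neutrophil genes, in edgeR fits of 2 libraries per strain.

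With 1 library left out at a time, changed genes ranged from 3099 to 3682, higher genes from 1561 to 1914, lower genes from 1493 to 1768, genes changed at least 2-fold from 1428 to 1537, leukotriene genes from 5 (without B6 3) to 8, neutrophil genes from 2 (without B6 3) to 4, lists past camera from 10 to 15 and the separation from 0.0223 to 0.0241. Members changed ranged from 13 to 16 for class I, 13 to 20 for xenobiotic metabolism, 8 to 11 for mast cells, 11 to 13 for tuft cells, 11 to 12 for Paneth cells, 10 to 12 for enteroendocrine cells, 19 to 20 for T cells and 2 to 3 for erythroid cells, with 9 for class II in each fit. Of 163 named genes 144 had passed; 117 of them passed in all 8 such fits and 27 were lost in at least 1. The only sign change among named genes that involved a call was Fabp4, whose log2 fold change ran from -0.60 (without C3H 3, adjusted p = 0.0416) to 1.05 (without C3H 1); C3H 3 held most of the fat transcripts. Without the 4 pancreas-rich libraries 88 of the 144 passed. Genes of few counts, such as Dpep3, Oxgr1 and Il13, did not pass the filter of the main fit.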

Other observations

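The tests of the mast cell, T cell, class II and 8-fold patterns below were chosen only after those results were seen; the count of neighbouring genes and the counts over other splits of the libraries were planned before.

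Changed genes lay next to each other on the chromosomes more often than in shuffles of the calls. Of 17718 tested genes in annotation order, 1087 adjacent pairs were both changed, against a mean of 805 and a maximum of 891 over 10000 shuffles (permutation p = 1e-04, the smallest they can give). Without copy families and unnamed models the count was 740 against a mean of 577 and a maximum of 653. Of the pairs, 62.6% moved in the same direction (61.2% without copies and unnamed models), against 50.1% and 49.96% in shuffles. Blocks of the genome that differ between the strains may explain this excess. The shuffles treat genes as independent of their neighbours, so other reasons for neighbours to change together cannot be told apart. Reads of C3H that failed to align to the B6-derived genome would lower counts in C3H and would not by themselves give the rises. Reads counted for a similar gene instead could raise that gene, which was not tested. Of the genes changed at least 8-fold outside copy families and unnamed models, 50.5% were lower in C3H (exact binomial interval 40.1 to 60.9, p = 1). This share covers 47 higher and 48 lower genes, of 154 and 152 changed at least 8-fold in all. It cannot tell whether the lower genes lost reads, and it leaves out the copy families.

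Mast cell genes were higher in C3H. Sharing of reads between near-identical protease genes was tested on the 10 list genes outside the protease families. Their mean log2 CPM was 0.94 higher in C3H (exact permutation p = 0.0286). Of the 10, 8 had a positive log2 fold change, and 6 of them passed the threshold with no filter on low counts. Some of these 10 had few counts, with 5 in B6 and 55 in C3H for Fcer1a and 6 and 42 for Ms4a2. RNA of mesenteric fat was tested by leaving out C3H 3, after which the fat list median was -1.52 and the mast cell median 2.66, with 8 genes higher. For RNA of pancreas, leaving out the 4 pancreas-rich libraries gave a mast cell median of 3.47 but did not remove the difference in the pancreas list (2.32). The test was therefore replaced, after its result was seen, by the spread of summed CPM among C3H libraries. There the mast cell list spanned 1.67-fold and the pancreas list 51.6-fold. Kit and Il1rl1, with 2597 and 1423 counts in C3H against 380 for Cpa3, weigh heavily in the mast cell sum, and other intestinal cells also express Kit. Over the C3H libraries Cpa3 ran from 1.53 to 2.42 CPM and Mcpt4 from 1.45 to 1.90. Mcpt2 ran more widely, from 2.71 to 8.79 CPM, and was highest in C3H 1, where the pancreas list was lowest among the C3H libraries. A larger number of mast cells, or more of these transcripts per cell, in C3H may explain the pattern and was not tested.

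T cell and intraepithelial lymphocyte genes were lower in C3H. Lymphoid follicles in B6 samples would bring B cells, but without B6 3, where 18 list genes were lower (median -1.03), the plasma and B cell list had a median of 0.11 (lower quartile -0.41), with 6 higher and 3 lower; this test replaced, after its result was seen, a count of lower T cell genes without B6 3 alone. A lower yield of all cells outside the epithelium would lower phagocyte, muscle, fibroblast and endothelial genes as well, but 55 of these had a median of 0.17 (quartiles -0.02 and 0.34). For failed alignment gene by gene, 10000 random lists of the same size and expression were drawn. None held 18 lower genes (maximum 9, median 2, permutation p = 1e-04, the smallest they can give). The list thus held more lower genes than such draws, which ignore that its members vary together. The draws cannot tell lost reads from lower expression, since the count table holds no reads. Fewer T cells and intraepithelial lymphocytes, or fewer of these transcripts per cell, in C3H may explain the pattern and was not tested.

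Most class II genes were lower in C3H. Cd74, which lies outside the H2 complex, fell by 1.82 on the log2 scale (-1.82, standard error 0.12). Its place fixes that it cannot lose reads through alleles of the complex, so this says nothing on lost reads within it, and reads lost from its own C3H allele were not tested. Within the complex, where 5 of 10 members were lower, lost reads and lower expression cannot be told apart, since the count table holds no reads. Fewer phagocytes would lower their markers, but their list had a median of 0.22, with 0 lower in edgeR. Lower interferon gamma signalling may contribute but cannot be told apart from other explanations. A list of 16 response genes had a median of -0.28 (upper quartile -0.10), with 5 lower (Gbp2, Ido1, Cxcl10, Socs1 and Irf8). Socs1 was lost without B6 3, B6 5 or C3H 5 (adjusted p up to 0.0729). Ifng itself had 22 counts in B6 and 4 in C3H and did not pass the filter of the main fit.

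Chance as the source of the number of changed genes was examined by refitting all 35 splits of the 8 libraries into 4 and 4. In each count tried, 1 of 35 splits, the real one, gave a result as large, and the highest of the other splits gave 0: 3857 changed genes, 1417 changed at least 2-fold, and 8 leukotriene, 9 class II, 16 class I, 19 xenobiotic, 3 erythroid, 10 mast cell, 13 tuft cell, 11 Paneth cell, 12 enteroendocrine, 20 T cell and 4 neutrophil genes. Chance was excluded for the number of changed genes at the level 35 splits allow. The other splits mix the strains, so the strain difference itself widens the spread within their groups; with 0 genes passing in any of them, the counts per list add no evidence of their own.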
